A study of Mus musculus with 9 samples.

How the data were processed

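RNA was sequenced from 9 libraries of mouse cortical neurons in 3 groups of 3 repeats. The groups were taken from the sample titles, which name a control, a peptide amphiphile (PA) and the peptide amphiphile with PS2 (PA + PS2). The treatment label reads peptide amphiphile for all 9 libraries, controls included, so it was not used. The labels do not say whether the repeats were separate cultures, so p-values measure the spread between these samples, which may be technical. The growth and treatment protocols give no times or amounts. The molecule label reads polyA RNA, while the extraction protocol names a kit for total RNA, so the RNA selection is not settled by the labels.

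The deposited values are raw read counts per Ensembl gene, with 1 file per library. Each file lists 54232 genes, and the values are whole numbers with no normalization. The notes of the authors name cutadapt 4.2, STAR 2.7.5, HTSeq 2.0.2, DESeq2 1.14.1 and the mouse genome build mm10, without roles or settings. The annotation release, strand setting and filters are not stated, so it is not known whether the counts separate genes that overlap on opposite strands. Gene names, coordinates and types came from GENCODE M21, which covers the same build and matched 54079 of the 54232 identifiers. The mitochondrial genes mt-Co2, mt-Co3, mt-Atp6 and mt-Nd3 had 0 counts in every file.

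Total counts ran from 20746851 to 27237398 per library. Levels are given in CPM, computed with edgeR from library sizes scaled by the trimmed mean of M values. In the shallowest library, 10 and 100 CPM correspond to 207 and 2070 reads, for which the counting error alone is 6.94% and 2.2%. Errors printed with mean CPM are standard deviations over the 3 libraries of a group. Errors printed with log2 fold changes are standard errors, taken as the absolute log2 fold change over the square root of the F statistic.

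The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, 2-sided, fitted to all 9 libraries at once with 6 residual degrees of freedom. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15712 genes and 99.9% of the counts. The scaling by the trimmed mean of M values (TMM) was the normalization of the main test. The p-values were adjusted by the method of Benjamini and Hochberg over the genes of a comparison, and genes with an adjusted p under 0.05 passed. The common coefficient of biological variation was 16.6%. The main test, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined, except where a choice is said to be later.

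The gene lists covered cell types, synapses, excitability, activity, adhesion, metabolism and stress. They numbered 36 and held 640 different symbols, of which 639 were in the files and 565 were tested, with 5 to 25 tested members per list. Each list was tested against all other genes with camera of limma 3.58.1 on voom values at its preset correlation of 0.01, adjusted over the 36 lists of a comparison. Members that passed were counted over all genes tested and again with p-values adjusted over the list alone. Camera with an estimated correlation and fry were alternatives. The PValue of fry tests whether the genes of a set move, on balance, in the same direction, and its PValue.Mixed tests whether they change in either direction; neither compares the set with other genes.

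Genes were named by a rule. It took up to 8 genes with the highest and 8 with the lowest log2 fold change among those that passed, with a mean of at least 1 CPM, groups that did not overlap, a protein-coding type and an ordinary symbol. It also took up to 4 members of each list with the smallest p, and, where fewer than 5 genes passed, the 5 genes with the smallest unadjusted p. A gene named in a comparison could be given in the others. Slc7a5, Slc3a2, Slc7a1, Aldh1l2, Atf5, Malat1 and Meg3 fall outside this rule and were chosen after their values were seen.

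The groups share the repeat numbers 1 to 3. Whether these pair the libraries was checked from the correlation of the deviations of each library from its group mean, across genes. For PA and control, the correlations of libraries with the same number were 0.42, 0.37 and 0.28. For PA + PS2 and control they were 0.18, 0.22 and 0.13. All were over 0.1, so in these comparisons a fit with the repeat as a block is printed beside a result wherever it changed the call of a gene or list given here, or moved by over 1.5 times a count of genes passing over all genes. The pairing is read from the data, since the labels do not say what the numbers mark. The fit with the block covers all 9 libraries, so it also pairs PA with PA + PS2. For these groups the correlations in repeats 1, 2 and 3 were 0.015, 0.29 and 0.3, which shows a pairing in repeats 2 and 3 but not in repeat 1. Not every pair was over 0.1, so for this comparison the block is given only with the dependence on processing.

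The test was checked on simulated data with the group sizes and depths of these libraries, in 5 simulations with 200 changed genes each. Each gene had the spread that edgeR estimated for it, and libraries were drawn independently. The test recovered 22.7% of genes changed 1.5-fold, 61.6% of those changed 2-fold and 87.2% of those changed 4-fold. Of its calls, 6.98% were false. In the unchanged comparison it made 2 calls over the 5 simulations. In the real data at most 7 genes passed in a comparison, and libraries that share a repeat number deviated together. The shares recovered need not hold there. A list of 20 genes changed 1.5-fold had a camera p under 0.05, not adjusted over the gene lists, in 5 of 5 simulations. An unchanged list did so in 1 of 5. The simulated genes of a list did not vary together. In PA + PS2 against control the estimated correlation was 0.24 for matrix genes and 0.75 for proliferation genes. Over all lists it ran from −0.04 to 0.99. The simulations therefore cannot tell how camera at its preset correlation performs on lists whose members vary together.

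The alternatives were DESeq2 1.42.0, size factors by relative log expression (RLE), no filter on low counts, a mean of at least 5 CPM, the repeat block, a fit to the 6 libraries compared, glmTreat against a fold of 1.2, limma-voom, and each library left out in turn. Leaving out all libraries of a repeat was added after the data were seen. Both comparisons with control use the same 3 control libraries, so their relation was set beside 20 simulations of unchanged groups. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No library was left out of the main test.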

Results

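Gene expression was measured by RNA sequencing in mouse cortical neurons labelled wild type and CD1, an outbred mouse stock. The 9 libraries fell into 3 groups of 3 repeats: control, PA, and PA + PS2. PA stands for a peptide amphiphile, a peptide joined to a fatty tail that assembles into fibres in water. The names of the PA libraries give IKVAV, a cell-binding sequence of laminin, and those of the PA + PS2 libraries give IKVAV plus PEDOT-S-OH. PEDOT polymers conduct electricity, and the labels do not spell out PS2 or the name PDL carried by the control libraries. The treatment label reads peptide amphiphile for the control libraries too, which conflicts with their titles, and the groups follow the titles.

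Total counts were 24282422, 22667191 and 21909305 in control repeats 1, 2 and 3. They were 22332749, 22970503 and 27237398 in the PA repeats and 20746851, 26123110 and 24627635 in the PA + PS2 repeats. Genes with at least 1 count numbered 22064 to 23223 in 8 libraries and 24702 in PA repeat 2. Mitochondrially encoded genes took 0.342% of the counts in PA repeat 1 and 0.531% in control repeat 1, against 0.786% to 1.39% in the other libraries. The correlation of log2 expression across genes was 0.975 to 0.99 within a group and 0.981 to 0.99 between libraries of different groups that share a repeat number. The first principal component held 31.7% of the variance, of which 31.4% lay between groups and 41.8% between repeat numbers. On the second, with 18.5% of the variance, 79.4% lay between repeat numbers. Every log2 fold change rests on 3 libraries per group and is given with its standard error, while levels in CPM are given with their standard deviation.

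PA was compared with control to ask how the peptide scaffold without PS2 related to gene expression in the neurons. No single gene passed the test, and 6 gene lists passed, each with a call that ended without at least 1 single library. The astrocyte list, named for the glia that clear glutamate and potassium, was higher in PA, with a median log2 fold change of 0.18 and 14 of 17 measured members above 0 (camera adjusted p = 1.7e-06; adjusted p = 0.71 with an estimated correlation). Its median level relative to the control mean was 0.23, 0.34 and 0.23 in PA repeats 1, 2 and 3 and −0.58, 0.27 and 0.40 in the controls, so control repeat 1 alone lay below all 3 PA libraries, and the call ended without it (0.403). Gfap, an intermediate filament of astrocytes, stood at 1.55 ± 0.69, with 2.38 CPM in PA against 0.824 CPM in control and 0.0822 CPM in control repeat 1. Aldoc, a glycolytic enzyme enriched in astrocytes, stood at 1.00 ± 0.40. Immediate-early genes, which neurons transcribe within minutes of activity, were lower, with a median of −0.37 and 16 of 17 below 0 (camera adjusted p = 0.00027; adjusted p = 0.71 with an estimated correlation). Without control repeat 1 their median was −0.09 and the call ended (0.403), as it did without PA repeat 3 (0.557). Egr1 stood at −1.22 ± 0.68, with 31.9, 9.56 and 6.22 CPM in the controls and 8.68, 6.37 and 5.49 CPM in PA, and Arc, a regulator of synaptic strength, at −0.93 ± 0.50.

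Another 4 lists were lower in PA. Delayed-response genes of neuronal activity had a median of −0.15, with 16 of 16 members below 0 (camera adjusted p = 0.0021; adjusted p = 0.71 with an estimated correlation), a call that ended without PA repeat 1 (0.182), control repeat 1 (0.306) or PA repeat 3 (0.23). Actomyosin genes and targets of the transcription factor SRF had a median of −0.19, with 17 of 18 below 0 (camera adjusted p = 0.001; adjusted p = 0.71 with an estimated correlation), and the call ended without PA repeat 3 (0.557). Genes of pericytes, fibroblasts and meninges had a median of −0.31, with 10 of 13 below 0 (camera adjusted p = 0.019; adjusted p = 0.71 with an estimated correlation). Among them Ogn, a matrix proteoglycan, stood at −1.07 ± 0.41, and the call ended without PA repeat 1 (0.103), control repeat 2 (0.124) or PA repeat 3 (0.613). Genes of choroid plexus and ependyma had a median of −0.73 over 7 members (camera adjusted p = 0.0067; adjusted p = 0.71 with an estimated correlation). Clic6, a chloride channel protein, stood at −1.76 ± 0.79, with 0.172 CPM in PA against 0.611 CPM in control. The choroid plexus call ended without control repeat 1 (0.0532), PA repeat 2 (0.209), PA repeat 3 (0.165) or control repeat 3 (0.384). In these 6 lists 0 members passed, over all genes or adjusted over the list alone, and no list passed with fry in either of its tests.

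Genes of neuronal structure and function did not pass in PA against control. The median was −0.01 for presynaptic release machinery (camera adjusted p = 0.38, its mean above 0), 0.01 for the glutamatergic postsynapse (0.4) and −0.03 for GABAergic neurons (0.16). It was 0.01 for voltage-gated channels (camera adjusted p = 0.37), 0.04 for axon growth and cytoskeleton (0.16) and 0.05 for cortical excitatory subtype markers (0.23). Nrgn, a calmodulin-binding protein of dendrites, was among the 5 with the smallest unadjusted p-values of the comparison, at 0.60 ± 0.17 and 14.4 ± 1.92 CPM against 9.43 ± 1.38 CPM in control (edgeR adjusted p = 1). Spp1, the secreted phosphoprotein osteopontin, had the smallest, at −1.76 ± 0.42 and 0.719 CPM against 2.43 CPM in control (edgeR adjusted p = 1). Gm15496, Gm49544 and Gm9800 completed these 5, all under 1 CPM. Matrix genes and YAP targets, described further for PA + PS2, had medians of −0.11 and −0.08 (camera adjusted p = 0.069 for both). Matrix genes passed, lower in PA, without PA repeat 1 (0.037), control repeat 1 (0.0133), PA repeat 2 (0.0311), PA + PS2 repeat 2 (0.0467) or PA + PS2 repeat 3 (0.0226). YAP targets passed, lower in PA, without PA repeat 1 (0.0196), control repeat 1 (0.0351), PA + PS2 repeat 2 (0.0467) or PA + PS2 repeat 3 (0.0204). Genes linked to reactive astrocytes, unlike the astrocyte list, had a median of −0.18, with 9 of 12 below 0 (camera adjusted p = 0.072). They passed, lower in PA, without control repeat 1 (0.00785) or PA repeat 2 (0.00892). The median, mean and test also differed in sign for proliferation genes (camera adjusted p = 0.71), the oligodendrocyte lineage (1) and interferon response (0.67). Proliferation genes passed lower in PA without control repeat 1 (6.91e-09) and higher without control repeat 2 (0.0259) or control repeat 3 (0.000103).

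By the edgeR test 0 of 15712 genes passed, with 192 at an unadjusted p under 0.05 where chance gives 786; DESeq2 and the fit with the repeat block also gave 0. Groups did not overlap for 635 genes, or 4.04%, where chance gives 10%. These chance values take the libraries as independent, whereas libraries that share a repeat number deviated together. Axon growth and cortical subtype genes passed, higher in PA, without PA repeat 2 (0.000467 and 0.000776), and GABAergic genes passed, lower in PA, without control repeat 2 (0.0194).

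PA + PS2 was compared with control to ask how the scaffold that carries both components related to gene expression. Lists of the extracellular matrix, of fibroblast-like and mural cells and of the contractile cytoskeleton were lower in PA + PS2 (adjusted p = 0.039 with an estimated correlation, and 0.11 with the repeat block as well). Each passed camera at its preset correlation both with and without the block. The medians of synaptic gene lists lay within 0.06 of 0. The list of dividing cells was lower by camera at its preset correlation alone (adjusted p = 0.19 with an estimated correlation), and 0 of its 24 members passed over all genes, against 13 with the repeat block. The edgeR test passed 7 genes, all lower in each of the 3 PA + PS2 libraries than in each of the 3 control libraries. Of these, 5 encode matrix proteins and 2 encode proteins that bind actin.

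Col5a2, a chain of fibrillar collagen V (ENSMUSG00000026042, mm10 chromosome 1, 45374321 to 45503282), fell by 1.78 ± 0.18 on the log2 scale, from 48.6 ± 5.97 to 14.1 ± 3.22 CPM (edgeR adjusted p = 0.011). Sparc, a collagen-binding matrix glycoprotein (ENSMUSG00000018593, chromosome 11, 55394500 to 55423183), fell by 1.96 ± 0.28, from 70.9 ± 16.9 to 18.2 ± 5.74 CPM (edgeR adjusted p = 0.037). Hspg2, which encodes the basement membrane proteoglycan perlecan (ENSMUSG00000028763, chromosome 4, 137468769 to 137570630), fell by 2.11 ± 0.30, from 32.3 ± 13 to 7.46 ± 2.14 CPM (edgeR adjusted p = 0.037). Col4a5, a chain of basement membrane collagen IV (ENSMUSG00000031274, chromosome X, 141475385 to 141689234), fell by 1.73 ± 0.23, from 7.44 ± 1.75 to 2.23 ± 0.247 CPM (edgeR adjusted p = 0.037). Thbs1, a secreted adhesive glycoprotein (ENSMUSG00000040152, chromosome 2, 118111876 to 118127133), fell by 1.08 ± 0.14, from 112 ± 20.8 to 52.8 ± 5.78 CPM (edgeR adjusted p = 0.034). The actin-binding gene Cnn2 (ENSMUSG00000004665, chromosome 10, 79988584 to 79996062) fell by 1.44 ± 0.19, from 20.6 ± 3.32 to 7.57 ± 1.49 CPM (edgeR adjusted p = 0.034). Palld, an organiser of actin bundles (ENSMUSG00000058056, chromosome 8, 61511433 to 61902690), fell by 1.2 ± 0.17, from 21.7 ± 3.34 to 9.42 ± 0.876 CPM (edgeR adjusted p = 0.037).

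**Figure D1:**
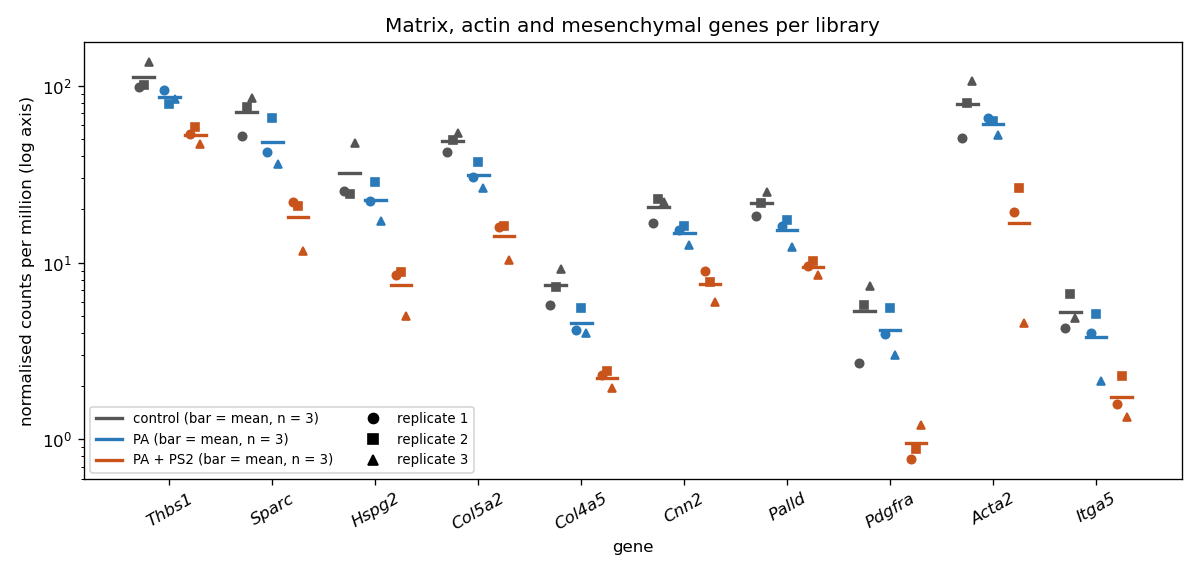
CPM (log axis) of 10 genes of matrix, adhesion and contractile cells in the 9 libraries, with a marker per library and a bar at the mean of each group of 3. For Sparc, the PA + PS2 libraries sit between 11.6 and 22.1 CPM and the control libraries between 52.1 and 85.0 CPM.

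Among 24 measured matrix genes the median log2 fold change was −0.80, and 23 were below 0 (camera adjusted p = 3.5e-26). Of these, 3 passed over all genes (10 with the repeat block) and 17 adjusted over the list alone. Nid1, a linker of laminin and collagen IV, stood at −1.80 ± 0.29 (edgeR adjusted p = 0.054, and 0.0085 with the repeat block), and Lamb2, a laminin chain, at −1.23 ± 0.23 (edgeR adjusted p = 0.083, and 0.015 with the block). Markers of pericytes, fibroblasts and meninges fell with them, with a median of −1.70 and 13 of 13 below 0 (camera adjusted p = 3e-19). Over all genes 0 of the 13 passed (6 with the block), and 10 passed adjusted over the list alone. Pdgfra, a growth factor receptor of fibroblasts and of oligodendrocyte precursors, stood at −2.46 ± 0.39 (edgeR adjusted p = 0.054, and 0.012 with the block). Acta2, the actin of smooth muscle, stood at −2.24 ± 0.46 (edgeR adjusted p = 0.11, and 0.03 with the block).

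Actomyosin genes and SRF targets had a median of −0.52, with 1 of 18 passing over all genes (10 with the block) and 11 adjusted over the list alone (camera adjusted p = 8.4e-19). Myl9, a myosin light chain, stood at −1.82 ± 0.35 (edgeR adjusted p = 0.086, and 0.023 with the block). Targets of YAP, a transcriptional regulator that responds to the stiffness of the substrate, had a median of −0.40 over 15 genes, of which 0 passed over all genes (5 with the block) and 7 adjusted over the list alone (camera adjusted p = 4.1e-11). Ccn1, a secreted YAP target, stood at −1.80 ± 0.27 (edgeR adjusted p = 0.054, and 0.0085 with the block). Integrins and laminin receptors had a median of −0.43 over 22 genes, of which 0 passed over all genes (5 with the block) and 7 adjusted over the list alone (camera adjusted p = 2.1e-10). Itga5, a subunit of the fibronectin receptor, stood at −1.60 ± 0.34 (edgeR adjusted p = 0.11, and 0.015 with the block) and Itgb5, a subunit of a vitronectin receptor, at −1.42 ± 0.28 (edgeR adjusted p = 0.097, and 0.01 with the block). These 5 lists (matrix, mesenchymal, actomyosin, YAP and integrin genes) each had an adjusted p = 0.039 with an estimated correlation. In the fit with the repeat block they each had an adjusted p = 0.11 with an estimated correlation. That fit has fewer residual degrees of freedom, so this value and 0.039 cannot be compared directly. At its preset correlation camera still passed all 5 with the block (adjusted p = 3e-26 for matrix genes and 1e-10 for YAP targets). All 5 passed fry for movement in the same direction and camera in all 9 fits that left out a library. The lists are not independent results, since some share members. Acta2, Tagln and Myl9 are in both the mesenchymal and the actomyosin list, and Vcl is in both the actomyosin and the integrin list.

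Genes of proliferation fell in PA + PS2, with a median of −0.96 and 24 of 24 below 0 (camera adjusted p = 6e-22; adjusted p = 0.19 with an estimated correlation). Over all genes 0 of the 24 passed (13 with the block), and 21 passed adjusted over the list alone. Cdk1, the kinase that drives entry into mitosis, stood at −1.23 ± 0.26 and 4.19 ± 0.843 CPM against 9.85 ± 2.98 CPM (edgeR adjusted p = 0.11, and 0.035 with the block). Mcm5, a subunit of the replicative helicase, stood at −0.75 ± 0.18 (edgeR adjusted p = 0.16, and 0.048 with the block). Genes of neural progenitors fell with a median of −0.61 (camera adjusted p = 8.5e-09; adjusted p = 0.25 with an estimated correlation), and 0 of 15 passed over all genes (3 with the block) and 8 adjusted over the list alone. Their members Nes and Vim, intermediate filaments of progenitors, stood at −0.91 ± 0.21 (edgeR adjusted p = 0.16, and 0.025 with the block) and −0.72 ± 0.12 (0.059, and 0.012 with the block). In the control libraries the median level of the proliferation genes, relative to the control mean, was −0.61, 0.25 and 0.32 in repeats 1, 2 and 3, and that of the progenitor genes −0.44, 0.22 and 0.21. In the PA + PS2 libraries the proliferation genes stood at −1.07, −0.83 and −0.78.

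**Figure D2:**
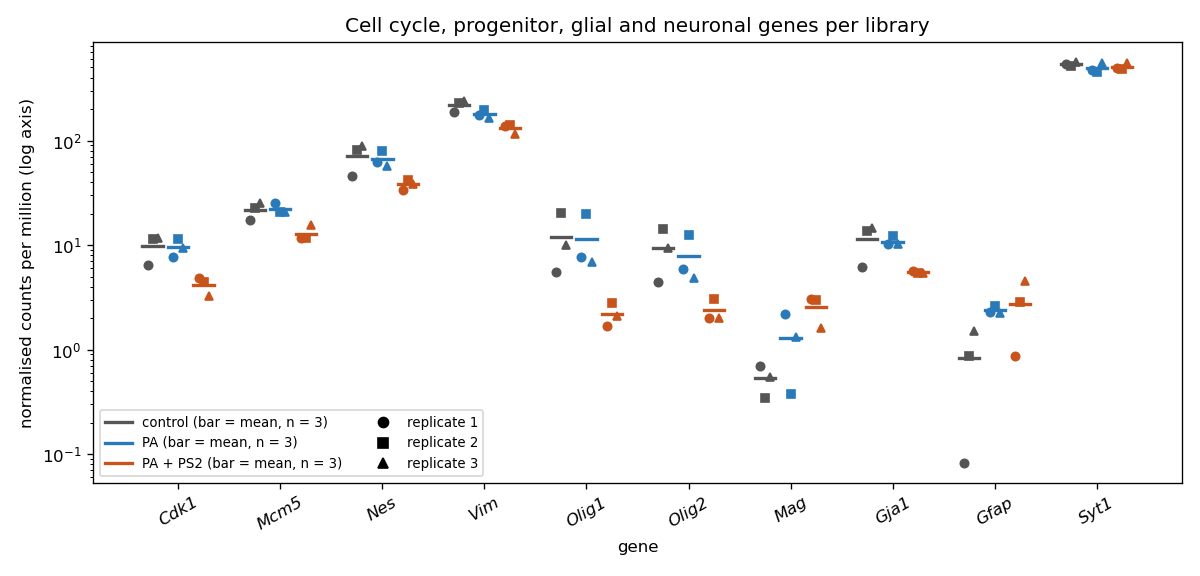
CPM (log axis) of 10 genes of dividing cells, progenitors, glia and neurons in the 9 libraries, with a marker per library and a bar at the mean of each group of 3. Olig1 lies between 1.68 and 2.78 CPM in PA + PS2 and between 5.59 and 20.1 CPM in control, while Syt1 shows a log2 fold change of −0.07 ± 0.10.

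Genes linked to reactive astrocytes fell with a median of −0.81 over 12 members, of which 0 passed over all genes (2 with the block) and 6 adjusted over the list alone (camera adjusted p = 2.9e-09; adjusted p = 0.13 with an estimated correlation). Its members with the smallest p, Vim and the membrane protein gene Emp1, are expressed beyond astrocytes, and Emp1 stood at −1.57 ± 0.35 (edgeR adjusted p = 0.13, and 0.035 with the block). General astrocyte genes had a median of −0.19 (camera adjusted p = 0.19), which passed with the repeat block (camera adjusted p = 0.045; adjusted p = 0.6 with the block and an estimated correlation) and without control repeat 1 (1.25e-05). Their levels in control repeats 1, 2 and 3 were −0.58, 0.27 and 0.40. Gja1, a gap junction protein of astrocytes, was the only member to pass adjusted over the list alone, at −1.06 ± 0.26 (edgeR adjusted p = 0.18). Gfap stood at 1.76 ± 0.69 (edgeR adjusted p = 0.65), with 2.75 CPM in PA + PS2 against 0.824 CPM in control. Genes of the oligodendrocyte lineage did not pass, with 2 higher and 4 lower adjusted over the list alone, a median of 0.10 and a mean of −0.21 (camera adjusted p = 0.92). Lists of microglia and macrophages (camera adjusted p = 0.16, median −0.11), endothelial cells (0.12, median −0.14) and choroid plexus and ependyma (0.72, median −0.15) did not pass, the last except without control repeat 2 (0.00383). Only 5 endothelial genes were tested, with a mean of −0.41, and 2 were lower adjusted over the list alone.

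The synaptic lists did not pass in PA + PS2 against control. Presynaptic release machinery had a median of 0.01 (camera adjusted p = 0.63) with a mean of −0.01, the glutamatergic postsynapse −0.06 (0.78), GABAergic neurons 0.05 (0.41) and voltage-gated channels −0.06 (0.45). Syt1, the calcium sensor of vesicle release, stood at −0.07 ± 0.10 and Camk2a, a kinase of the postsynapse, at −0.26 ± 0.10 (edgeR adjusted p = 0.58). Cortical excitatory subtype markers rose with a median of 0.08 and 14 of 18 above 0 (camera adjusted p = 0.021; adjusted p = 0.53 with an estimated correlation), among them the neuronal transcription factor gene Neurod2 at 0.31 ± 0.15. Genes of axon growth and cytoskeleton rose with a median of 0.07 and 18 of 23 above 0 (camera adjusted p = 0.02; adjusted p = 0.53 with an estimated correlation), among them Nefm, a neurofilament, at 0.41 ± 0.17. The axon call ended without control repeat 2 (0.0586) or PA + PS2 repeat 3 (0.28). The subtype call ended without control repeat 1 (0.105), control repeat 2 (0.0596) or PA + PS2 repeat 3 (0.177). In these lists 0 members passed, over all genes or adjusted over the list alone.

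Immediate-early genes were lower in PA + PS2 than in the same controls, with a median of −0.27 and 15 of 17 below 0 (camera adjusted p = 0.0034; adjusted p = 0.59 with an estimated correlation), and 1 passed adjusted over the list alone. Arc, which was not that member, stood at −1.16 ± 0.51 (edgeR adjusted p = 0.81). Btg2, also a member of the list of neural progenitors, fell from 15.8 ± 1.8 to 9.66 ± 1.78 CPM. Delayed-response genes had a median of −0.19 (camera adjusted p = 0.029; adjusted p = 0.59 with an estimated correlation) and neurotrophin signalling genes −0.23 (camera adjusted p = 0.035; adjusted p = 0.4 with an estimated correlation), each with 0 members passing adjusted over the list alone. The immediate-early call ended without control repeat 1 (0.678) or PA + PS2 repeat 3 (0.142). The delayed-response call ended without control repeat 1 (0.578), PA + PS2 repeat 2 (0.0907), control repeat 2 (0.156) or PA + PS2 repeat 3 (0.0743). The neurotrophin call ended without PA + PS2 repeat 1 (0.11), control repeat 1 (0.395), control repeat 2 (0.095) or PA + PS2 repeat 3 (0.0617). In control repeats 1, 2 and 3 the median level of immediate-early genes was 0.43, 0.14 and −0.58. Within repeats 1, 2 and 3 the median log2 ratio of PA + PS2 to control was −0.21, −0.70 and 0.01.

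Cholesterol synthesis genes were higher in PA + PS2, with a median of 0.17 and 19 of 21 above 0 (camera adjusted p = 1.7e-06; adjusted p = 0.19 with an estimated correlation), with Mvd, an enzyme of the mevalonate pathway, at 0.37 ± 0.13 and Acat2, which makes acetoacetyl-CoA, at 0.30 ± 0.12. Nuclear genes of oxidative phosphorylation had a median of 0.08 and 18 of 18 were above 0 (camera adjusted p = 0.0035; adjusted p = 0.53 with an estimated correlation), a call that ended without control repeat 2 (0.428) or PA + PS2 repeat 3 (0.241). No member of either list passed, over all genes or adjusted over the list alone. Targets of the antioxidant regulator NRF2 had a median of 0.08 (camera adjusted p = 0.078) and ribosomal protein genes 0.08 (0.13), and both passed with the repeat block (0.048 and 0.03; adjusted p = 0.24 and 0.37 with the block and an estimated correlation). Ribosomal protein genes also passed without control repeat 1 (0.00232) or PA + PS2 repeat 2 (0.0267), and NRF2 targets without PA + PS2 repeat 1 (0.0414), PA + PS2 repeat 2 (0.0267) or control repeat 3 (0.0405).

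The other lists did not pass in PA + PS2 against control. Lysosome and autophagy genes had a median of 0.05 (camera adjusted p = 0.11), metallothionein and metal response genes −0.15 (0.27) and glutamate and potassium clearance transporters −0.10 (0.81). Hypoxia and glycolysis genes had a median of −0.02 (0.49), mitochondrially encoded genes −0.26 (0.68) and heat shock proteins −0.01 (0.92). The median, mean and test differed in sign for unfolded protein and integrated stress response (camera adjusted p = 0.24), p53 targets (0.68), interferon response (0.92) and NF-kB and cytokine genes (0.78). NF-kB and cytokine genes passed the mixed test of fry (adjusted p = 0.0013), with the chemokine gene Ccl5 at 1.38 ± 0.61 and Nfkb2, a subunit of NF-kB, at −1.35 ± 0.32. Ccl5 lay at very low levels, with 0.493 CPM in PA + PS2 against 0.19 CPM in control and 0.0435 CPM in control repeat 2. Without control repeat 1 the mitochondrially encoded (0.0348) and lysosomal genes (0.00705) passed, and the lysosomal genes also without PA + PS2 repeat 2 (0.0219).

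By the edgeR test 884 genes had an unadjusted p under 0.05 in PA + PS2 against control, 171 higher and 713 lower, where chance gives 786. The fit with the repeat block passed 184 genes, 18 higher and 166 lower, and DESeq2 passed 232, 21 higher and 211 lower; each included the 7 genes, and 151 genes were shared by both. Groups did not overlap for 1873 genes, or 11.9%, where chance gives 10%. The count was 175 without control repeat 1 and 18 without PA repeat 1, and it was 0 without PA + PS2 repeat 1, control repeat 2 or control repeat 3. Without PA + PS2 repeat 2 it was 2 and without PA + PS2 repeat 3 it was 1. Col5a2 passed in 6 of the 9 fits that left out a library, with log2 fold changes of −1.96 to −1.52 over all alternatives, and the other 6 genes each passed in 4 of the 9. Over all alternatives the highest adjusted p was 0.56 for Col5a2 and Hspg2, 0.81 for Col4a5 and 0.61 for the other genes.

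**Figure D3:**
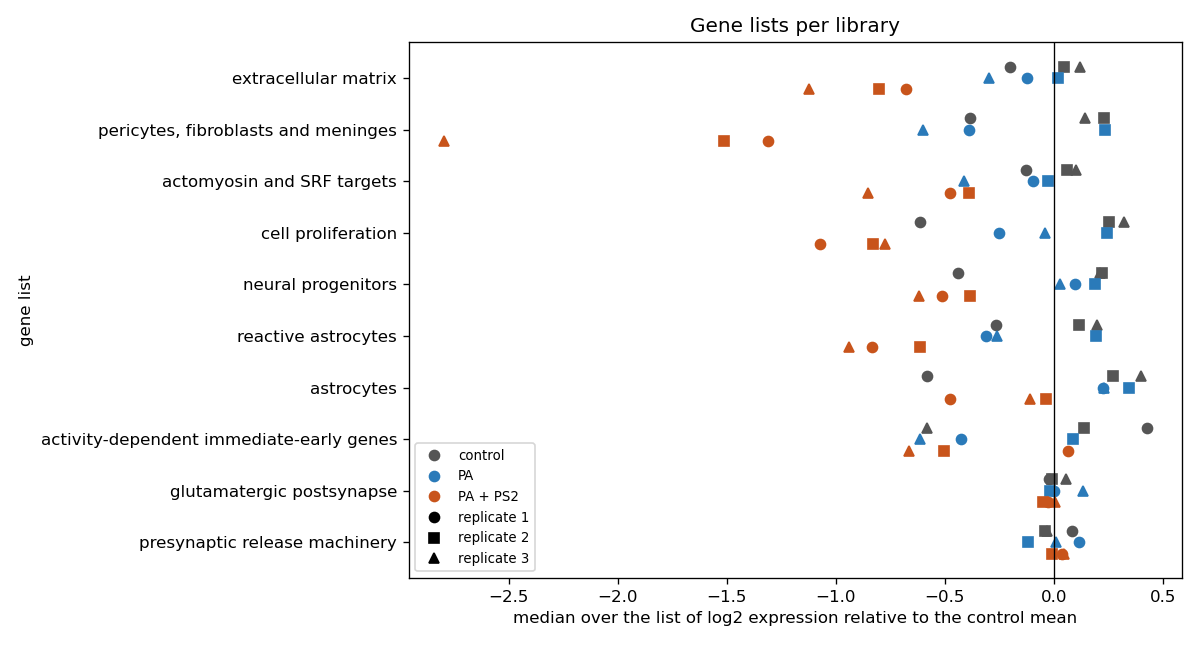
Median log2 expression of 10 gene lists in each of the 9 libraries, relative to the mean of the 3 control libraries, with a marker per library. Matrix genes lie between −1.12 and −0.68 in PA + PS2 and between −0.20 and 0.12 in control, while proliferation and astrocyte genes are lower in control repeat 1 (−0.61 and −0.58) than in the other controls.

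PA + PS2 was compared with PA to ask how adding PS2 to the peptide scaffold related to gene expression. No gene passed the edgeR test. The lists of matrix, mesenchymal, cell cycle and astrocyte genes were lower in PA + PS2 by camera at its preset correlation. No list was under an adjusted p = 0.11 with an estimated correlation. Among these lists, matrix genes alone also passed a test of fry, the mixed one (adjusted p = 0.026). Proliferation genes fell with a median of −0.95, with 21 of 24 lower adjusted over the list alone (camera adjusted p = 2e-22; adjusted p = 0.22 with an estimated correlation). Cdk1 stood at −1.18 ± 0.26 and Mcm3, another helicase subunit, at −1.11 ± 0.25 (edgeR adjusted p = 0.25 for both). Matrix genes fell with a median of −0.66 and 15 of 24 lower adjusted over the list alone (camera adjusted p = 1.9e-22; adjusted p = 0.11 with an estimated correlation), with Lamb2 at −1.15 ± 0.23, Sparc at −1.40 ± 0.28 and Hspg2 at −1.61 ± 0.30. Col5a2 stood at −1.15 ± 0.18 (edgeR adjusted p = 0.24).

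Markers of pericytes, fibroblasts and meninges fell with a median of −1.31 and 5 of 13 lower adjusted over the list alone (camera adjusted p = 2.1e-13; adjusted p = 0.11 with an estimated correlation), with Pdgfra at −2.12 ± 0.39. Actomyosin genes fell with a median of −0.33 and 7 of 18 lower alone (camera adjusted p = 6.4e-12), integrins with −0.37 and 5 of 22 (1.3e-07), and YAP targets with −0.30 and 5 of 15 (4.3e-08). These 3 lists each had an adjusted p = 0.11 with an estimated correlation. Neural progenitor genes fell with a median of −0.45 and 7 of 15 lower adjusted over the list alone (camera adjusted p = 1.3e-10; adjusted p = 0.22 with an estimated correlation), among them Tead2, a partner of YAP, at −1.30 ± 0.23 and Eomes, a transcription factor of intermediate progenitors, at −1.10 ± 0.23. Astrocyte genes fell with a median of −0.64 and 6 of 17 lower adjusted over the list alone (camera adjusted p = 1.3e-07; adjusted p = 0.23 with an estimated correlation), among them Aldh1l1, a folate enzyme of astrocytes, at −1.16 ± 0.33. Genes linked to reactive astrocytes had a median of −0.56 and 2 of 12 lower adjusted over the list alone (camera adjusted p = 2.5e-06; adjusted p = 0.22 with an estimated correlation). These lists and those of matrix and proliferation passed camera in all 9 fits that left out a library.

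GABAergic genes rose in PA + PS2 against PA with a median of 0.11 and 16 of 20 above 0 (camera adjusted p = 0.029; adjusted p = 0.29 with an estimated correlation), a call that ended without PA repeat 2 (0.346) or PA + PS2 repeat 3 (0.245). Cholesterol synthesis genes rose with a median of 0.10 (camera adjusted p = 0.0018; adjusted p = 0.29 with an estimated correlation), a call that ended without PA + PS2 repeat 2 (0.169). Genes of the unfolded protein and integrated stress response had a median of 0.00, a mean of 0.10 and an upward test (camera adjusted p = 0.029; adjusted p = 0.27 with an estimated correlation). Of these, 3 were higher adjusted over the list alone, among them Asns, the asparagine synthetase gene, at 0.50 ± 0.10, and the call ended without PA repeat 3 (0.203) or PA + PS2 repeat 3 (0.0976). Presynaptic (camera adjusted p = 0.97), glutamatergic (0.33), channel (0.15), axon growth (0.31) and cortical subtype genes (0.25) did not pass, with medians of 0.03, −0.05, −0.01, 0.04 and 0.04. Axon growth (0.0412) and subtype genes (0.047) passed, higher in PA + PS2, without PA repeat 1. Besides presynaptic and stress response genes, the median, mean and test differed in sign for delayed-response genes (camera adjusted p = 0.77), the oligodendrocyte lineage (0.91), mitochondrially encoded genes (0.77), heat shock proteins (0.98) and p53 targets (0.097). Gpnmb, a glycoprotein of macrophages and melanocytes, had the smallest p of the comparison at 2.09 ± 0.27, with 7.49 ± 2.48 CPM against 1.75 ± 0.121 CPM (edgeR adjusted p = 0.1).

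By the edgeR test 0 genes passed between PA + PS2 and PA, with 881 at an unadjusted p under 0.05, 162 higher and 719 lower; DESeq2 passed 136, 10 higher and 126 lower. Without control repeat 1, which enters the fit through the shared spread, 37 genes passed, and without PA + PS2 repeat 2, 2 passed.

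**Figure D4:**
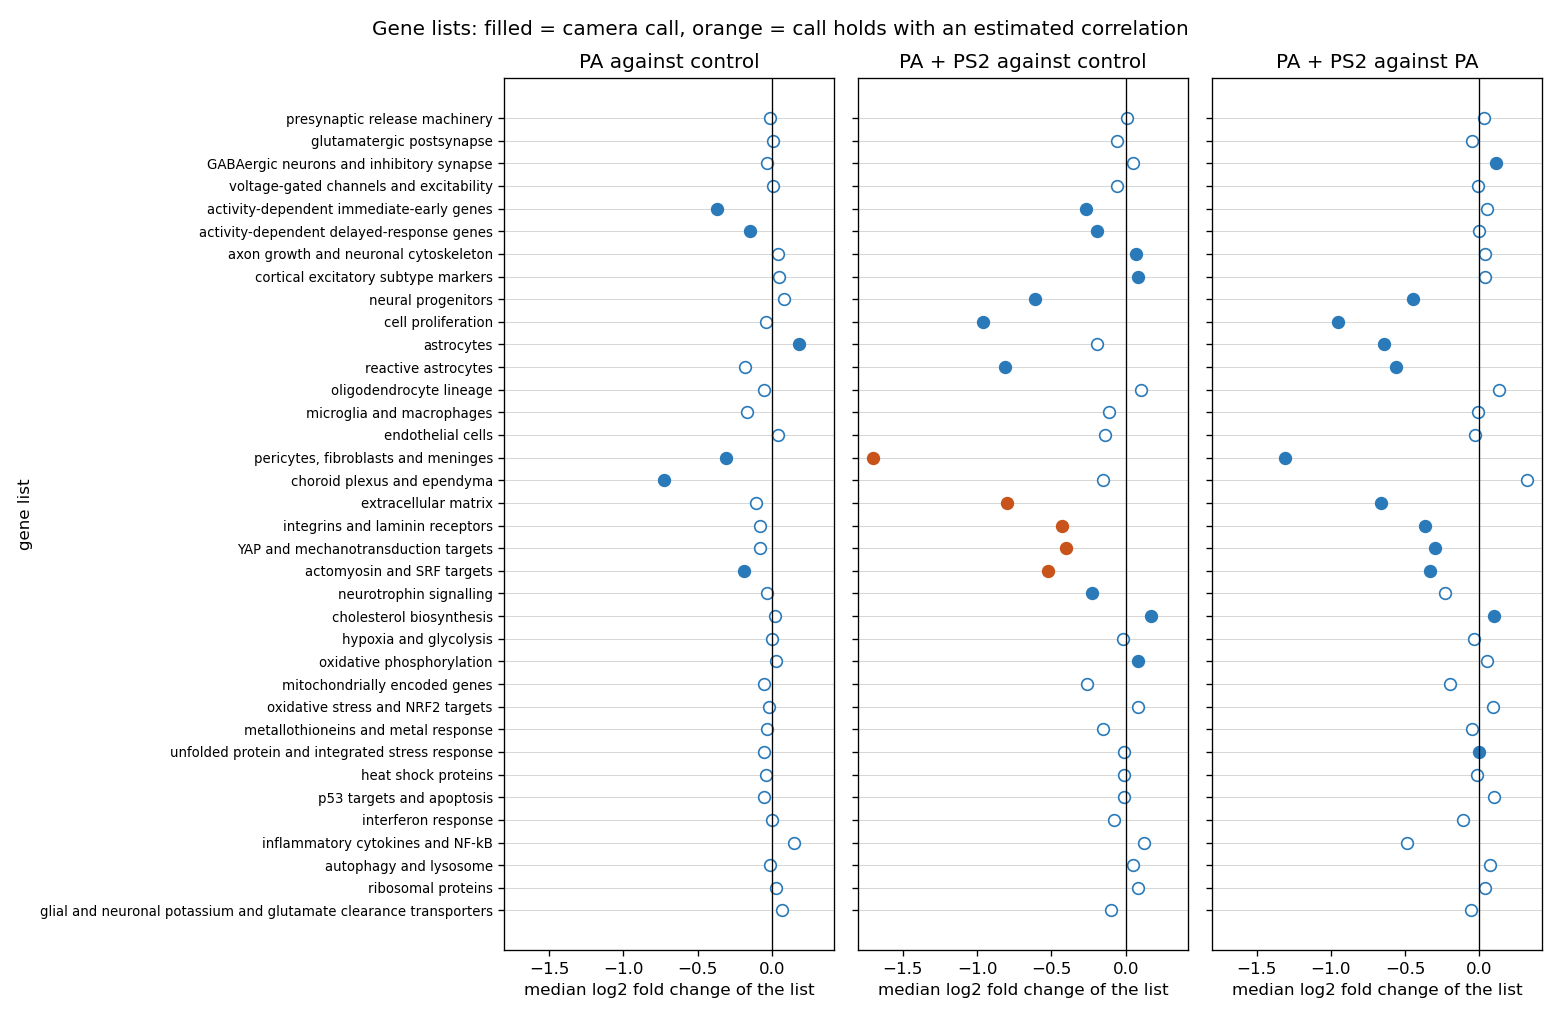
Median log2 fold change of each of the 36 gene lists in the 3 comparisons, with filled points for lists that passed camera at its preset correlation and orange points for those that also passed with an estimated correlation. Passing lists number 6 in PA against control, 15 in PA + PS2 against control and 12 in PA + PS2 against PA, and the 5 that held with an estimated correlation are all in PA + PS2 against control.

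The comparisons of PA and of PA + PS2 with control share the same 3 control libraries, which alone makes their values alike. Their log2 fold changes had a correlation of 0.39 across 15712 genes, which are not independent replicates, while simulations of unchanged groups against shared controls gave 0.482 to 0.519. Their covariance was 0.0399, below the simulated 0.0439 to 0.0491, and simulations link the groups by the controls alone. Libraries that share a repeat number also deviated together, which changes the value to be set beside the covariance, so it is not read as a difference. With 0 genes passing in PA against control, none could be shared. Of the 7 genes that passed in PA + PS2, Col5a2 stood at −0.63 ± 0.18, Col4a5 at −0.70 ± 0.22 and Sparc at −0.57 ± 0.27 in PA against control, with an edgeR adjusted p of 1 for each. The comparisons that share the PA + PS2 libraries had a correlation of 0.743, where simulations without such a link by repeat gave 0.479 to 0.515.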

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

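The fits that left out all 3 libraries of a repeat were chosen after the results were seen; the other alternatives were planned. In PA against control the count of genes moved from 0 only without a filter on low counts, to 23. With PA + PS2 and control it moved from 7 to 232 with DESeq2, 17 with RLE size factors, 365 without a filter, 184 with the repeat block and 28 in a fit to the 6 libraries compared. It was 1 each with a mean of at least 5 CPM, with glmTreat and with limma-voom, and 0 to 175 with a library or repeat left out. Between PA + PS2 and PA it moved from 0 to 136 with DESeq2, 330 without a filter and 57 with the block, and lay between 0 and 37 with a library or repeat left out. Genes shared by both comparisons with control numbered 9 without a filter and 0 in every other fit. Without a filter the prior degrees of freedom of the edgeR fit became infinite, against a median of 5.59 with it, so the spread of each gene was set by the trend alone; the cause of the other moves was not tested.

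Lists passing in PA against control numbered 0 with an estimated correlation, 0 with either test of fry and 1 to 12 with a library or repeat left out, against 6. For PA + PS2 and control they numbered 5 with an estimated correlation, 5 with fry, 8 with its mixed test and 9 to 17 with a library or repeat left out, against 15. For PA + PS2 and PA they numbered 0, 0, 3 and 10 to 19, against 12. The estimated correlation allows for members that vary together, but this alone need not account for the lower counts. For p53 targets the estimated correlation was −0.03 in each comparison, below the preset one. Their unadjusted camera p moved from 0.049 to 0.079 in PA + PS2 against PA and from 0.12 to 0.14 in PA against control. In PA + PS2 against control it moved from 0.55 to 0.54. How much of the drop in lists comes from members that vary together was not tested. RLE size factors, the block and a mean of at least 5 CPM kept each count of lists within 1.5 times. Some list tests passed in the opposite direction, or turned from a passing one, in fits that left out a library or repeat. In PA against control the adjusted p over these fits ran from 1.85e-08 to 0.976 for delayed-response genes, 0.00202 to 0.713 for neural progenitors, 6.91e-09 to 0.785 for proliferation and 0.000571 to 0.957 for mitochondrially encoded genes. In PA + PS2 against PA it ran from 5.87e-09 to 0.997 for mitochondrially encoded genes. No named gene turned in a fit in which it passed. Beyond the values given with the results, the block changed no other call of a list in the comparisons with control, nor of a gene whose value is printed for them; genes not printed that passed with it are among the 184.

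For PA + PS2 and PA, the correlations between libraries with the same number were 0.015, 0.29 and 0.3, and that of repeat 1 was below its 0.14 with another number. Repeats 2 and 3 each correlated best with their own number, but not every pair was over 0.1, so the block is given only here. Of the genes named for this comparison it passed Gpnmb (edgeR adjusted p = 0.015), Col5a2 and Mcm3 (0.029 each), Tead2 (0.033), Lamb2, Pdgfra and Sparc (0.035 each) and Eomes (0.044). It passed 13 lists and added neurotrophin signalling (camera adjusted p = 0.028; adjusted p = 0.34 with the block and an estimated correlation), and 0 of the 13 passed with an estimated correlation. The depth limits genes of low level: at 10 CPM the counting error alone is 6.94%. In simulations the test recovered 22.7% of genes changed 1.5-fold, so genes that did not pass are not shown to be unchanged.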

Other observations

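The tests of matched genes, of receptor genes, of depth and of other splits were planned before their results were seen; the tests of single libraries, nuclear RNAs, differences within repeats and mesenchymal transcription factors were chosen after, the last in place of 6 markers that belong to the lists themselves. The list of unfolded protein and integrated stress response genes did not pass in PA + PS2 against control (camera adjusted p = 0.24), with a median of −0.01 and 12 of 20 members below 0. Some of its members, and related genes (Slc7a5, Slc3a2, Slc7a1, Atf5 and Aldh1l2) chosen after their values were seen, had values above 0 that did not pass the edgeR test without the repeat block; of the 20 members, 2 passed over all genes with it. Slc7a5 and Slc3a2, which together form a transporter of large neutral amino acids, stood at 0.53 ± 0.11 (edgeR adjusted p = 0.11, and 0.023 with the repeat block) and 0.37 ± 0.10 (0.24, and 0.049 with the block). Slc7a1, a carrier of arginine and lysine, stood at 0.43 ± 0.10 (edgeR adjusted p = 0.13, and 0.023 with the block). Atf4, the transcription factor of the amino acid response, stood at 0.43 ± 0.10 (edgeR adjusted p = 0.16, and 0.03 with the block), and the related Atf5 at 0.41 ± 0.10 (0.18, and 0.037 with the block). Among genes known to respond to Atf4, Asns stood at 0.42 ± 0.10 (edgeR adjusted p = 0.17, and 0.073 with the block), Chac1, which degrades glutathione, at 0.62 ± 0.19 (0.35, and 0.035 with the block) and Aldh1l2, a mitochondrial folate enzyme, at 0.53 ± 0.19 (0.5, and 0.03 with the block). In PA against control the same 8 genes lay between −0.08 and 0.23.

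The list of the oligodendrocyte lineage did not pass in PA + PS2 against control (camera adjusted p = 0.92; 0.071 in the mixed test of fry), and 0 of its 15 members passed the edgeR test over all genes, against 4 with the repeat block and 5 with DESeq2. Olig1 and Olig2, transcription factors of its precursors, stood at −2.42 ± 0.51 (edgeR adjusted p = 0.11, and 0.0069 with the block) and −1.97 ± 0.45 (0.14, and 0.0095 with the block) against control, and the precursor proteoglycan Cspg4 at −1.43 ± 0.37 (0.2, and 0.079 with the block). Mag, a myelin protein, stood at 2.24 ± 0.55 (edgeR adjusted p = 0.17, and 0.048 with the block), with 2.54 ± 0.796 CPM against 0.533 ± 0.176 CPM. The list of microglia and macrophages did not pass either, with a median of −0.11 and 7 of 14 members above 0 (camera adjusted p = 0.16). Its members ran from −1.96 to 0.95. Among these, Cx3cr1, a chemokine receptor of microglia, stood at −1.96 ± 0.60 (edgeR adjusted p = 0.33) and C1qb, a complement protein, at −1.32 ± 0.41 (0.37). Both lay at very low levels, with 0.346 and 0.343 CPM in PA + PS2 against 1.32 and 0.861 CPM in control. The list member Tyrobp went the other way, with 0.915 ± 0.469 CPM in PA + PS2 against 0.47 ± 0.234 CPM in control. Outside the list, the lysozyme gene Lyz2 stood at 2.27 ± 0.39 (edgeR adjusted p = 0.061, and 0.015 with the block) and Gpnmb at 1.12 ± 0.26 (0.15, and 0.04 with the block).

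The matrix, mesenchymal and proliferation lists held 61 tested genes, with a median log2 fold change of −1.06 in PA + PS2 against control and −1.05 with the repeat block. Genes outside the lists matched on expression, GC content and exonic length had a median of −0.06 in both fits, which argues against a bias of these properties as the whole cause. Of the 303 matched genes 0 passed, but 10 passed lower with the repeat block, beside 166 of all 15712 genes. The median of the 61 genes was still −0.98 without the PA + PS2 library whose absence weakened it most, which argues against a single such library. Of 19 transcription factors of mesenchymal identity outside the lists, 4 had enough counts to be tested (Prrx1, Foxc1, Foxf2 and Tbx18), and their median was −1.42, so fewer mesenchymal cells in the PA + PS2 cultures is a candidate explanation for the matrix and mesenchymal part. None of the 4 passed the edgeR test and 3 lay under 1 CPM in control, while Acta2 stood at 79.0 CPM there and 16.8 CPM in PA + PS2, and the labels name no sort that would remove such cells. A lower level within each cell was not tested and stays open for all of these genes, as does the cause for the proliferation genes.

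PA repeat 2 had counts for 24702 genes, against at most 23223 in the other 8 libraries. Olfactory and vomeronasal receptor genes, silent in cortex, had counts for 82 genes there and 45 to 82 in the others. This fell short of the excess set beforehand for genomic DNA, but these numbers were not adjusted for depth. Their summed counts, 440 against at most 365, were the highest of the 9. Genes outside the protein-coding type took 1.79% of the counts there and 1.16% to 1.59% in the others, so genomic DNA stays open. After thinning all libraries to the lowest total PA repeat 2 still held 24447 genes against 21671 to 23096, which argues against depth. Long nuclear RNAs had a median log2 ratio of 0.79 to the median of the other libraries, with 8 of 8 higher and 0.29 the highest such median of another library, so more nuclear RNA in this library may account for it. Mitochondrially encoded genes, however, also took their highest share of the 9 libraries there, 1.39% against 1.34% in control repeat 3. A larger nuclear share alone would not raise these, so the explanation is not settled. Malat1 stood at 737 CPM there and at 132 to 425 CPM elsewhere. No biological explanation was tested, since the labels set this library apart in nothing but its number.

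The lower immediate-early genes in PA, with a median of −0.37, may rest on a single control library. Without control repeat 1 the median was −0.09, against −0.43 without control repeat 2 and −0.55 without control repeat 3. Within repeats 1, 2 and 3 the median log2 ratio of PA to control was −0.77, −0.10 and −0.12, so 2 repeats lay below −0.1, between the outcomes set for a difference in a single repeat and in all. An effect of PA on neuronal activity stays open and was not tested.

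The 6 libraries of a comparison can be split in 10 ways, too few for a share under 0.05. In PA against control the real split gave 0 genes and 6 lists, the highest other split 7 genes and 12 lists, and 10 and 8 splits gave as many. In PA + PS2 against control the real split gave 7 genes and 15 lists, the highest other split 0 genes and 16 lists, and 1 and 2 splits gave as many. In PA + PS2 against PA the real split gave 0 genes and 12 lists, the highest other split 0 genes and 14 lists, and 10 and 3 splits gave as many. Where the numbers pair the libraries, 4 splits part all 3 pairs, and the others leave pairs together. Among these, with the block, the real split of PA + PS2 and control gave 184 genes and 18 lists and the highest other 0 genes and 15 lists, while that of PA and control gave 0 genes and 6 lists and the highest other 0 genes and 12 lists.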
